A study of Lacticaseibacillus casei str. Zhang with 4 samples.

How the data were processed

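Lacticaseibacillus casei strain Zhang, a lactic acid bacterium, was grown in glucose-supplemented milk, and total RNA was hybridised to 1-colour (Cy3) Agilent oligonucleotide arrays. Per the labels, there were 2 biological replicates at 14 h (late logarithmic phase, pH 5.2) and 2 at 18 h (stationary phase, pH 4.5). Groups and replicate numbers were taken from those labels.

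The deposited scanner output held linear intensity values for each spot, produced per the file headers with Agilent Feature Extraction 10.5.1.1, and the processed signal used here is the background-subtracted intensity of that software. The deposited value table of the series held intensity values too, and each of its values divided by the processed signal of the same spot lay between 0.995 and 1.005. Its scale is therefore that of the unscaled processed signal, with medians of 157, 186.5, 379 and 281 over all 15534 features on the 14 h replicates 1 and 2 and the 18 h replicates 1 and 2. Any further normalization by the authors is not given in the sources used here.

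Each array carried 14998 spots of 6763 distinct probes besides 536 control spots. Of these probes, 6740 were spotted 2 times and 23 were spotted 66 times. Spots marked as outliers made up 0.667% and 0.660% of the probe spots at 14 h and 0.360% and 0.433% at 18 h and were left out, and no spot was saturated. The number of arrays, 2 per group, limits the precision. At 14 h the spread of log2 differences between replicates, after centring, was 0.138 in set A (sets are defined further on) against 0.106 for duplicate spots within an array, and in set B 0.118 against 0.128, The offset between sets differed between replicates too, and it enters the comparison of all probes, whose standard error was 0.169 against medians of 0.086 in set A and 0.078 in set B for the comparison within sets. The labels call the replicates biological, but the sample titles leave open whether the 2 arrays of a time came from separate cultures, and each SD and p-value then measures only the spread between these arrays, which may be technical. At 18 h these values were 0.130 against 0.084 in set A and 0.120 against 0.094 in set B.

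The log2 processed signal was reduced by each array's 75th percentile over the probe spots, and spots of a probe were averaged. A probe was tested when it was well above background on both arrays of at least 1 group. Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment, a threshold of 0.05 and no covariate. Counts are also given for a log2 difference of at least 1, which is 2-fold. In this comparison limma estimated no variation of the variance between probes and gave every probe the same standard error, with 9628 degrees of freedom from 4 arrays. Adjusted p-values as small as those it gives come from this pooling over probes. These choices, the rule for named genes and most alternatives were fixed before the data were examined.

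The files do not pair the probes with genes. Probes carry only a number and a sequence of 60 bases. None of the probe names (0 matches) occurs in the table of 2890 genes supplied for another strain of the species (assembly ASM82905v1), which holds no sequences. The planned tests of gene lists could not be run for that reason, and no gene is named. The rule for named genes asked for the largest changes with every 18 h array beyond every 14 h array, and it was applied to the probes, limited to 2 that rose and 2 that fell.

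After the data were seen, probes were divided by number, because their signal changed in steps along the numbering. The 14 h mean log2 level was split by recursive change-point search, with at least 20 probes per set and a gain of at least 100 times the variance. The same boundaries were found from the 18 h level. With the levels shuffled along the numbering, 0 of 100 runs found a boundary. With levels redrawn within the sets found here, 96 of 100 runs found the 3 boundaries all within 10 probes. These redrawn levels came from the division itself, so that rate shows only that the search can find such steps. A second limma comparison was then run within each set, after each array was centred on the median of the set's probes that were well above background on all 4 arrays.

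The main comparison was tested on simulated data with the levels of its 4814 probes. Of 100 probes changed by 1 on the log2 scale, 74 were recovered, and of 100 changed by 2, 97 were recovered, with 6 calls among 4614 unchanged probes. The simulated noise was drawn independently for each probe, with no offset shared by the probes of a set. Its variance also differed between probes, whereas the real comparison gave every probe the same standard error. These rates therefore do not give the power or the false calls of the real comparison.

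All 4 arrays lay on 1 slide and were read in 1 scan, so slide and scan could not act as blocks. The 14 h arrays lay in slide row 1 and the 18 h arrays in slide row 2, so slide row and group cannot be told apart. Each slide column held 1 array of each time: column 3 held 14 h replicate 1 and 18 h replicate 2, and column 4 the other 2 arrays. Alternatives covered background correction by normexp with an offset of 50, other scalings, other filters, the variance model, a replicate block, leaving out each array and the deposited value table.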

Results

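RNA from milk cultures labelled L. casei Zhang was measured with 2 arrays at each time. The times were 14 h, in the late logarithmic phase at pH 5.2, and 18 h, in the stationary phase at pH 4.5. Of the 14998 probe spots on each array, 69.8% and 70.7% were well above background at 14 h and 71.8% and 71.3% at 18 h. Across the 4814 tested probes, Pearson's r between replicates was 0.997 at both times, and r between arrays of different times lay between 0.916 and 0.934. These are correlations across probes, which are not independent replicates.

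Blocks of consecutive probe numbers, here called sets A to D, differed in signal. Set A, probes 1 to 1992, was the brightest, with a median log2 signal of 11.73 ± 0.013 (SD, n = 2) at 14 h and 11.28 ± 0.127 (SD, n = 2) at 18 h. Set B, probes 1993 to 4808, had a median of 7.69 ± 0.222 (SD, n = 2) at 14 h and 8.92 ± 0.321 (SD, n = 2) at 18 h. Set C, probes 4809 to 6713, lay at background, with 8.16% of its probes well above background at 14 h and 7.72% at 18 h. Set D, the 50 probes from 6714 to 6763, had a median of 9.36 ± 0.304 (SD, n = 2) at 14 h and 10.63 ± 0.379 (SD, n = 2) at 18 h. The files give no description of these sets and do not say which belongs to the labelled strain. Counts over all probes are therefore not counts of genes of that strain.

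**Figure D1:**
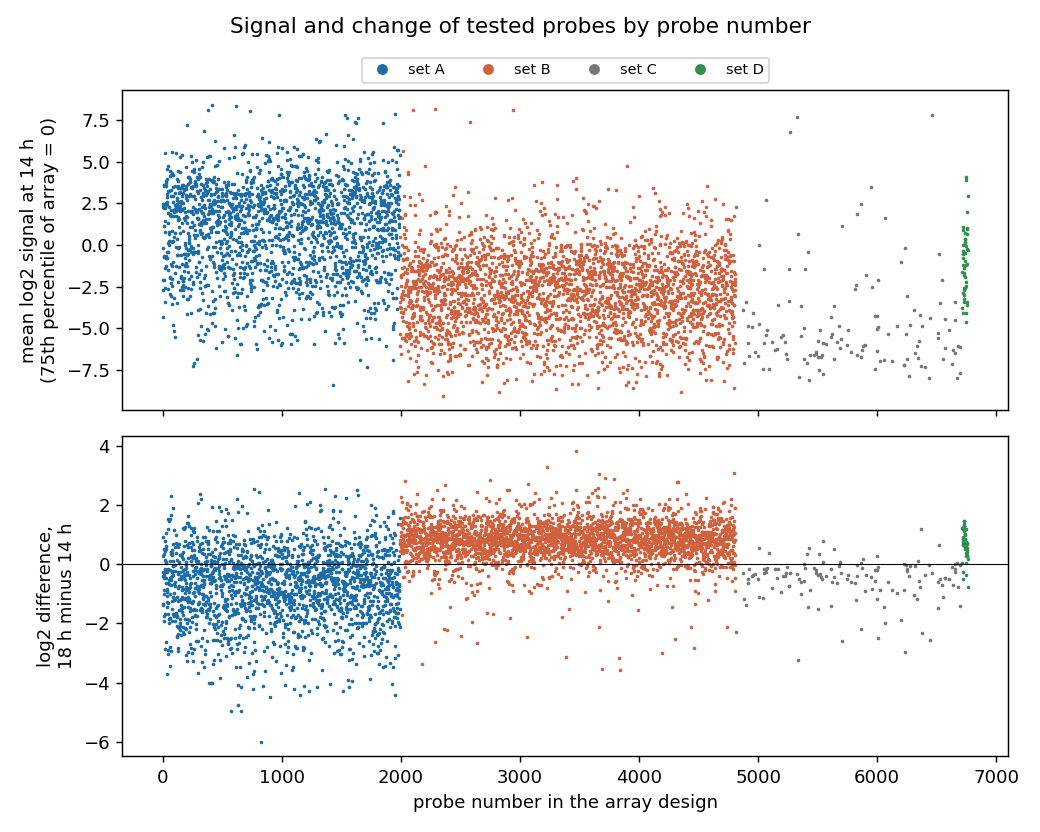
Upper panel, mean log2 signal at 14 h of each tested probe relative to the array's 75th percentile, against the probe number. Lower panel, log2 difference between 18 h and 14 h of the same probes. Points are probes, coloured by set, and both the level and the difference step at probe 1992.

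The comparison of 18 h with 14 h asks how probe signal changed from the late logarithmic to the stationary phase. With each array scaled to its 75th percentile, 2586 probes were higher and 1358 were lower at 18 h among 4814 tested (limma, adjusted p below 0.05), and 870 did not pass. Of those, 1067 were higher and 809 lower by at least 2-fold, and this balance turned with the setting. The counts were 399 higher and 1123 lower with median scaling, 414 and 755 with normexp background correction, 695 and 780 with quantile normalization, and 2288 and 503 with the percentile taken over probes well above background on all arrays. The direction followed the probe sets. In set B, 2212 of 2725 tested probes were higher and 111 lower, and in set A 330 of 1910 were higher and 1168 lower. In set D, 35 of 46 were higher and 3 lower, and in set C 9 of 133 were higher and 76 lower. These counts depend on the scaling. Among probes well above background on all arrays, 26.8% of set A had a positive difference with this scaling and 44.0% unscaled. The 97 such probes of set C had a median unscaled difference of 0.07. Higher probes made up 65.6% of the probes past the threshold. That share was 49.2% with median scaling (1664 higher, 1716 lower) and 78.3% with the percentile taken over probes well above background on all arrays (3221 higher, 894 lower).

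The offset between sets does not depend on a scaling factor per array. The median log2 signal of set B minus that of set A, over probes well above background on all arrays, was -4.00 ± 0.269 (SD, n = 2) at 14 h and -2.33 ± 0.173 (SD, n = 2) at 18 h. It rose by 1.67, a 3.18-fold change in the ratio, and both 18 h arrays lay above both 14 h arrays. This value compares set medians. Measured as the gap between the median differences of the sets' probes, the shift was smaller, at 1.45. Within slide column 3 the offset of set medians rose by 1.738 and within slide column 4 by 1.602. The exact two-sided permutation test gave p = 0.333, the smallest p that 2 arrays against 2 allow. The offset of set D minus set A rose by 1.83, from -2.42 ± 0.274 to -0.59 ± 0.311 (SD, n = 2 each; exact permutation p = 0.333). Set D minus set B differed by 0.16, from 1.58 ± 0.0046 to 1.73 ± 0.138 (SD, n = 2 each), a difference close to the spread of the 18 h replicates. Set A held 82.7% ± 1.15 of the summed signal at 14 h and 75.1% ± 1.87 at 18 h (SD, n = 2 each), and set B held 13.6% ± 1.11 and 20.9% ± 2.08 (SD, n = 2 each).

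**Figure D2:**
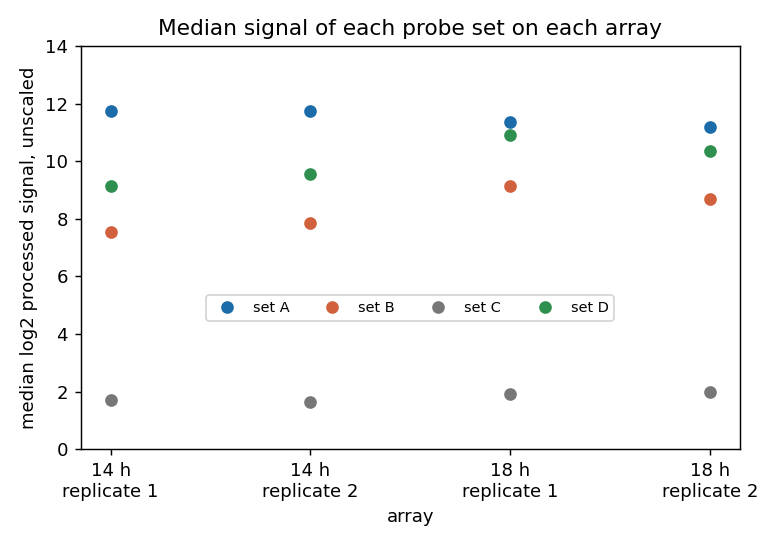
Median log2 processed signal of each probe set on each of the 4 arrays, before scaling. Each point is the median of the set on 1 array. Sets B and D are higher on both 18 h arrays than on both 14 h arrays, while set A is lower.

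The unscaled median difference of set A was -0.17 on the log2 scale and that of set B was 1.28. With the 75th percentile scaling they were -0.65 and 0.80, with median scaling -1.06 and 0.39, and with quantile normalization -0.49 and 0.52. With the percentile taken over probes well above background on all arrays, they were -0.14 and 1.31. Set B was above set A in each, but scaling by 1 factor per array cannot change the gap between the sets. Only quantile normalization could have changed it. The sign of neither set changed between these scalings. At equal brightness the sets also differed. For probes with a mean log2 signal from 8 to 10, the unscaled median difference was -0.16 over 372 probes of set A and 1.23 over 954 probes of set B, and from 12 to 14 it was -0.23 over 566 and 0.94 over 117.

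Within sets, after each array was centred on the set's median, 1650 of 1910 probes of set A passed the limma threshold, 1015 higher and 635 lower. In set B 1790 of 2725 passed, 1080 higher and 710 lower. Centring moves all probes of a set on an array by the same amount, so calls near the shift turn. Of the 1168 set A probes lower in the comparison of all probes, 635 were lower and 274 higher within the set, and of the 2212 set B probes higher in it, 1080 were higher and 208 lower within the set. The balance of higher and lower depended on the centring. When the median difference was set to 0, the counts were 805 higher and 827 lower in set A and 876 higher and 856 lower in set B. With normexp background correction set B had 611 higher and 783 lower. In set D 12 of 46 were higher and 24 lower, but 16 were higher and 14 lower when the median difference was set to 0, and 13 and 12 with quantile normalization within each set.

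After this centring, changes of at least 2-fold were more frequent in set A than in set B. They covered 40.8% of the tested probes in set A and 9.76% in set B. Before it, in the comparison of all probes, they covered 44.7% in set A and 36.0% in set B, where the offset between the sets is included. The centring does not alter the spread within a set, and the SD of the within-set log2 difference was 1.21 in set A and 0.66 in set B. In the 4 pairings of a 14 h array with an 18 h array, the share lay between 39.6% and 42.1% in set A and between 9.32% and 11.5% in set B. Between replicates of the same time, 0.052% of set A probes and 0.330% of set B probes differed at least 2-fold at either time. With normexp background correction the shares were 36.6% in set A and 5.72% in set B.

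**Figure D3:**
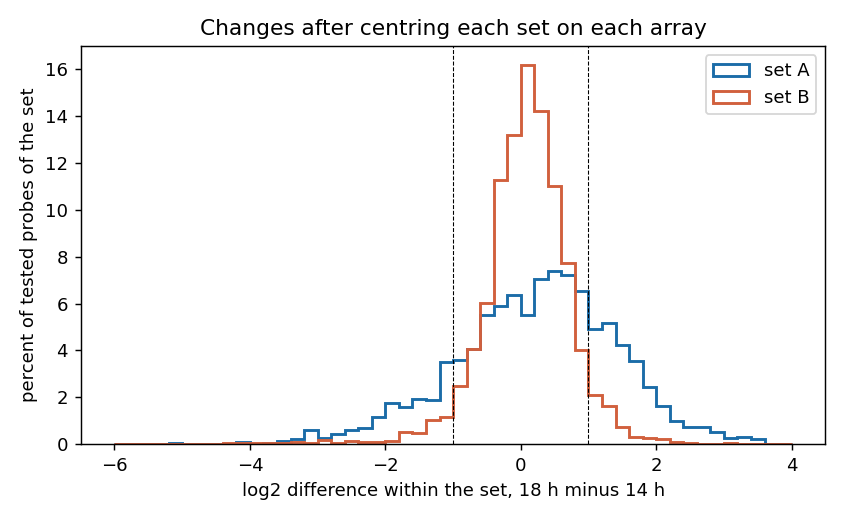
Distribution of the log2 difference between 18 h and 14 h within sets A and B, as the percent of the set's tested probes per bin, after centring each array on the set's median. Dashed lines mark 2-fold changes, which 40.8% of set A and 9.76% of set B reached.

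The largest rises in the comparison of all probes were in set B. The ranking of rises and falls there includes the offset between the sets, so it does not rank changes within sets. After centring within sets, 492 probes of set A and 145 of set B were higher by at least 2-fold, and 287 and 118 were lower. Probe cust_03471 rose by 3.83 on the log2 scale (SE 0.169, limma adjusted p = 5.55e-108), from -3.23 ± 0.141 to 0.60 ± 0.0013 relative to the 75th percentile (SD, n = 2 each), and by 3.12 within its set (SE 0.130, limma adjusted p = 9.95e-05). Probe cust_03223 rose by 3.29 (SE 0.169, limma adjusted p = 1.38e-80) and by 2.59 within its set (SE 0.133, limma adjusted p = 0.00012). With normexp background correction its rise was 1.72, and 1.22 within its set. The largest falls were in set A. Probe cust_00825 fell by 5.99 (SE 0.169, limma adjusted p = 3.52e-254), from 3.30 ± 0.493 to -2.69 ± 0.338 (SD, n = 2 each), and fell by 5.03 within its set (SE 0.180, limma adjusted p = 2.51e-06). Probe cust_00661 fell by 4.97 (SE 0.169, limma adjusted p = 6.79e-178) and fell by 4.01 within its set (SE 0.107, limma adjusted p = 1.98e-06). The SE of 0.169 and the adjusted p-values in the comparison of all probes rest on a variance pooled over all probes. That SE is the same for every probe, so it does not measure the spread of a single probe. For cust_00825 the adjusted p-value ranged from 2.41e-278 to 6.18e-05 over the other settings, the latter with median scaling. All 4 probes were flagged well above background on all 4 arrays. Probe cust_03223 was dim at 14 h, with unscaled signals of 23.1 and 37.0 against array medians of 182 and 217. The size of its rise is therefore less certain.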

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

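All tests weighed in this part were chosen after the result they bear on was seen. Control probes were not part of the comparisons. The spike-in control probe (+)E1A_r60_a22 had a mean log2 signal of 7.49 and lay above every negative control spot on all 4 arrays. The labels mention no spike-in RNA.

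Set B rose against set A between 14 h and 18 h. Several technical explanations are argued against by the tables. A response that depends on brightness alone would shift set A probes as bright as those of set B, but the smallest gap between the sets in any brightness bin was 0.553 on the log2 scale, in the brightest bin with 24 set B probes. The gap was 1.63 from log2 levels of 10 to 12 and 1.17 from 12 to 14. This argues against brightness as the whole cause, while a partial effect of brightness stays open. Between probes of like GC content, from 35% to 50%, the smallest gap was 1.14. Over probes with 1 open reading frame, GC at the third codon position averaged 36.2% in set A (1147 probes) and 43.1% in set B (1623 probes). This argues against 2 sets of probes for the same genes, for the probes with such a frame. At equal brightness from log2 levels of 4 to 14 the difference was at least 3.75 percentage points. That binned value cannot decide, since bins of sets with unlike levels could hold different genes. A change in the shares of RNA from 2 sources stays open: the sets also differed between replicates of 1 time, by at least 0.174 at equal brightness, but these differences follow the slide column at both times, and an effect of the array or its column that differs by set would give the same. Slide row cannot be told apart from time because 0 slide rows held arrays of both times.

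After centring within sets, set A changed at least 2-fold more often than set B. At equal brightness from log2 levels of 4 to 14 the share in set A was at least 3.74 times that in set B, which argues against brightness there. Above 14, with 24 set B probes, the ratio was 1.72 and leaves brightness open. Measurement noise between arrays is argued against by the 0.052% of set A probes that differed at least 2-fold between replicates, but spread between cultures stays open, since the replicates of a time may share a culture. Binding of set A RNA to set B probes, which could damp their changes, stays open. In the brightest bin set B changed 0.580 times as often as set A, but this is the ratio of 1.72 inverted. It is no separate test and cannot tell such binding from brightness. A difference in the response of the cells to the stationary phase stays open as well.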

How the results depend on the processing

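The results within sets, the set offset, the crossed pairing and the centring on the median difference were chosen after the data were seen. Across 15 settings the count of probes higher at 18 h stayed within 1.5 times the main 2586 in 14, and the count lower within 1.5 times 1358 in 14. The exceptions were 1664 higher with median scaling and 894 lower with the percentile over probes well above background on all arrays, where only the scaling factor differed. Leaving out 1 array at a time, with the lone array assumed to vary like the other group, gave 2338 to 2514 higher and 1171 to 1390 lower. The set offset fell to 1.06 under quantile normalization between arrays, which forces the arrays to 1 distribution, and lay between 1.06 and 1.86 over all settings. Within set B normexp gave 611 higher; the cause was not tested. Counts in set A stayed within 1.5 times in all 15 settings. The share of probes changed at least 2-fold lay between 36.6% and 41.7% in set A and between 5.72% and 11.3% in set B. Set D has few probes: its lower count was 15 with the replicate block, 12 with quantile normalization within each set (13 higher) and 14 with centring on the median difference (16 higher), which turned the balance, and without 1 array 6 to 8 were higher and 12 to 18 lower. Each of the named probes kept its direction and its side of the threshold in every setting that was run, but normexp lowered the rise of cust_03223 to 1.72.

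The labels give a replicate number, which does not show whether arrays of the same number are related. Deviations of same-numbered arrays correlated at -0.55 across all tested probes, a value that includes the offset between sets. After centring they correlated at -0.26 in set A, -0.17 in set B and -0.73 in set D. The replicate block gave 2420 higher and 1260 lower. The crossed pairing, which is also the position across the slide, gave 2792 higher and 1475 lower. Scaling to spike-in probes was not run because most of them lay below the highest negative control spot on every array. Slide and scan blocks were not run because there was 1 of each, and the median of a gene's probes and the gene list tests because no probe was paired with a gene. Low signal limits what set C can show.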

Other observations

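The tests of hypotheses in this part, and the division into sets, were chosen after the data were seen. Set C lay at background, yet 97 of its 1905 probes were well above background on all 4 arrays, with a median unscaled log2 difference of 0.07. The 10 brightest probes of set C carried 97.7% of the set's signal, and 12 of its probes had a mean log2 signal above 10. In the comparison of all probes, 54 of the 97 were lower and 2 higher at 18 h.

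At 14 h the offset of set B minus set A differed by -0.38 between replicate 1 and replicate 2, and at 18 h it differed by 0.24. At both times the offset was higher on the array in slide column 4, at -3.81 against -4.19 at 14 h and -2.20 against -2.45 at 18 h. The gap had the same sign in every brightness bin, from -0.36 to -0.23 at 14 h and from 0.17 to 0.34 at 18 h.

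A hypothesis was that set B is the probe set of the labelled species. It held 190 more probes than the 2626 protein-coding genes in the table of another strain, while set A held 1992 probes and set C 1905. Numbers of genes differ between strains, so the comparison leaves this open. Third-position GC, over probes with 1 open reading frame, averaged 36.2% in set A and 43.1% in set B. It averaged 53.4% in set C (1045 probes) and 38.8% in set D (30 probes). The sets thus differed in composition, but with no sequences of the species at hand these values cannot tell which set is its own.

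Another hypothesis was that probes encoding hydrophobic or basic peptides changed with a direction of their own. Reading frames were assigned to 98.4% of set A and 99.3% of set B probes. Where more than 1 frame was open, codon use decided. On probes with 1 open frame, codon use picked that frame for 87.9% in set A and 88.7% in set B. The codon use was learned from those same probes, so some peptides may be misassigned. With an estimated correlation, camera gave an adjusted p of 0.979 for each of the 4 tests, in sets A and B. The medians of the 47 hydrophobic and 126 basic probes of set A differed from the other probes by -0.03 and -0.13, and those of the 132 hydrophobic and 127 basic probes of set B by -0.09 and -0.04.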
